A study of Mus musculus with 17 samples.

How the data were processed

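Single cells of the brain immune fraction were measured in 17 mice, 8 given vehicle and 9 given silibinin, with 1 sample per mouse. Per the labels, the mice were 10 weeks old and of the C57BL/6J strain, melanoma cells of the B16/F10-BrM line had been injected into the brain, and silibinin was given daily by oral gavage at 200 mg/kg from day 3 after injection. Per the labels' protocols, cells were either sorted as live CD45-positive CX3CR1-negative cells or depleted of CX3CR1-positive cells with magnetic beads. The labels do not say which mice went through which route, and both routes are meant to remove microglia and part of the macrophages, so myeloid shares are set in part by the separation. Libraries were made with a targeted immune panel on the BD Rhapsody platform, per the labels' protocols.

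The deposited values are counts of reads per panel gene and cell, after the platform's distribution-based error correction as the deposited tables' names say. They are reads and not molecules, so PCR copies of a molecule are not independent and intervals on shares cover counting error only. The aligner, the pipeline version, the genome build and the cell calling are not given in the sources used here. Each deposited table had 397 panel columns. The 2 Tigit amplicons were summed, which left 396 genes, named here by the symbols in the tables.

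Cells with reads of at least 10 panel genes were kept, which were 3709 of the 5710 deposited cells. Reads of each cell were scaled to 10000, log-transformed and reduced to 20 principal components in scanpy 1.11.5, and cells were clustered with 15 neighbours and the Leiden method at resolution 1.0. A cluster was called X-like when at least 3 markers of a list stood among its 10 leading genes by fold, among genes seen in at least 10% of its cells, with the microglia list joined to that of monocytes and macrophages. T-like clusters were divided into CD8 and CD4 where cells with reads of one lineage outnumbered the other by at least 2 to 1, and a T-like cluster that met neither bound was called undivided. A cluster led by NK genes with Cd3d reads in over 50% of its cells stayed unnamed. These naming bounds were set after seeing the data. Of 17 clusters, 14 were named. No doublets were removed. Scrublet's own threshold called 1801 cells (48.6%) doublets, which was not usable, so an alternative left out the 202 cells with the highest scores instead.

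Shares of each class were compared between groups with a two-sided exact permutation test over all 24310 splits of the mice, with Benjamini-Hochberg adjustment over the 8 named classes of at least 100 cells. For genes, reads were summed over the cells of a set in each mouse with at least 10 cells of that class, and sets with at least 3 such mice per group were fitted with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, glmQLFit with robust estimation and glmQLFTest, Benjamini-Hochberg threshold 0.05). Fold changes are silibinin over vehicle on the log2 scale with their standard errors, and log2 CPM values carry a prior count of 2. A total of 17 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, and with fry from limma 3.58.1, where at least 4 members were tested. The lists were cytotoxic effector, inhibitory receptors and exhaustion, T cell activation and costimulation, lymphocyte cytokines, interferon response, STAT3 pathway and targets, naive and memory T cell, tissue residency, regulatory T cell, chemokines, chemokine receptors, MHC class II and antigen presentation, proliferation, inflammatory myeloid, immunosuppressive myeloid, immediate early genes, and apoptosis.

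The tests, the lists, the cell type markers, the rule for named genes and a set of alternatives were chosen before the data were examined. By that rule, in all cells and in CD8 T-like cells up to 12 genes past the threshold in each direction were named in order of p, and where fewer than 8 passed, genes with the smallest unadjusted p were added up to 8 and given as values. In each other class the rule took up to 4 passing genes per direction or, where none passed, the 2 with the smallest unadjusted p. A set of 17 genes was named wherever tested in the first 2 sets, of which 2, Socs3 and Timp1, were not on the panel. Members of a described list with the smallest p were added. DESeq2 1.42.0, other scalings, other filters, per-cell means in limma, a block on the replicate number, other cell calls and leaving out each mouse were among those alternatives.

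The labels name no batch. The share of nonzero entries under 10 reads split the mice into 2 technical batches without reference to group: 0.484% to 3.23% in batch 1 (4 vehicle and 4 silibinin mice) and 9.61% to 12.7% in batch 2 (4 vehicle and 5 silibinin mice). Finer differences in read scale per gene gave 6 runs. In batch 1 each of the 4 runs held 1 vehicle and 1 silibinin mouse. The main tests did not use this matching. Fits with batch or run as a term, permutations within batch and each batch alone were added after seeing the data. The edgeR fit and camera were tested on simulated sums of reads per mouse, drawn for each gene independently. Cells, clustering, class shares, permutation tests, technical batches and correlation between genes were not simulated. Camera's preset test found 5 of 5 lists shifted 4-fold in all cells and 5 of 5 in CD8 T-like cells. It also called 3 of 80 other lists in all cells and 0 of 65 in CD8 T-like cells. With all cells (362 genes), 18% of genes set to differ 2-fold were called, 58% at 4-fold, 84% at 8-fold and 88% at 16-fold, with 6 false calls among 1590 unchanged genes. With CD8 T-like cells (212 genes), the shares were 8%, 46%, 62% and 72%, with 2 false calls among 822.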

Results

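The series measured immune cells from the brains of mice carrying intracranial melanoma, with and without silibinin, a plant flavonolignan that the series uses to inhibit the transcription factor STAT3. The comparison asks how the makeup and the gene expression of the separated immune fraction differ with the drug. There were 8 vehicle mice and 9 silibinin mice. Total reads per mouse ran from 1489056 to 16527114, and kept cells from 38 in silibinin 9 to 448 in vehicle 6. Median reads per kept cell lay between 9283 and 37111. S100a8, a calcium-binding protein that neutrophils carry in very large amounts, took from 3.77% of a mouse's reads in silibinin 9 to 55.7% in silibinin 6.

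The kept cells formed B-like cells (939), CD4 T-like cells (431), CD8 T-like cells (416), NK-like cells (346), monocyte or macrophage-like cells (299), neutrophil-like cells (298), undivided T-like cells (236), dendritic-like cells (197) and mast cell or basophil-like cells (33). B-like cells were led by Ighd, the heavy chain of surface IgD, and Fcer2a, the low-affinity IgE receptor CD23. CD4 T-like cells were led by Il17a, Il17f and Rorc, genes of the interleukin-17 programme, with Ctla4 and Icos, T cell checkpoint and costimulatory receptors. Of the CD4 T-like cells 48.7% had Cd4 reads and 5.80% reads of Cd8a or Cd8b1. Il17a had reads in 37.4% of them, Rorc in 20.4% and Il17f in 13.2%, so these genes do not describe the whole class. CD8 T-like cells were led by Gzmk, Cd8a and Cd8b1, undivided T-like cells by the naive T cell genes Lef1 and Tcf7, and NK-like cells by the granzymes Gzma and Gzmb. The CD8 T-like cluster was not pure: 262 of its cells had reads of Cd8a or Cd8b1 and none of Cd4, 92 had Cd4 reads and none of Cd8, 3 had both and 59 had neither. A cluster of 318 cells with NK receptor genes among its leading genes stayed unnamed, as did 2 smaller clusters. Cd3d, a CD3 subunit of the T cell receptor complex, had reads in 89.3% of the 318 cells. Microglia were not told apart from macrophages: in a cluster of 172 of the monocyte or macrophage-like cells 100% had reads of the complement gene C1qa and 68.0% of Cx3cr1, the fractalkine receptor, both on the microglia list.

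B-like and CD8 T-like cells showed the smallest p-values among the cell classes, in opposite directions. B-like cells averaged 29.2% ± 14.5 (SD, n = 8) of kept cells in vehicle mice and 17.6% ± 6.53 (SD, n = 9) in silibinin mice. CD8 T-like cells averaged 9.66% ± 4.44 (SD, n = 8) and 14.4% ± 4.07 (SD, n = 9), with 8 of 9 silibinin mice above the vehicle median. In neither class did the difference pass after adjustment over 8 classes. For B-like cells the exact permutation p was 0.0374 (adjusted 0.157), and for CD8 T-like cells it was 0.0392 (adjusted 0.157). Percent of lymphoid cells was an alternative to the main denominator, chosen in advance because the separation can set myeloid shares. By it CD8 T-like cells made up 14.1% ± 5.68 (SD, n = 8) in vehicle and 23.5% ± 5.23 (SD, n = 9) in silibinin mice. All 9 silibinin mice lay above the vehicle median there, with an exact permutation p of 0.004 (adjusted 0.02 over 5 classes). The unnamed cluster of 318 cells, most with Cd3d reads, was not counted as lymphoid. With it in the denominator the difference was 7.05 percentage points in place of 9.44 (adjusted exact p = 0.0428). The call among lymphoid cells also depended on how the class was drawn and on the cell filter. With cells of at least 20 genes and clusters drawn again the difference was 4.17 percentage points (adjusted exact p = 0.367). With a Leiden resolution of 1.5 it was 3.69 points (adjusted p = 0.414), and with cells assigned by reads of lineage genes it was 3.18 (adjusted p = 0.35), both by exact permutation. Over all other cell calls and denominators tried, the adjusted exact p ran from 0.0054 to 0.414.

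**Figure D1:**
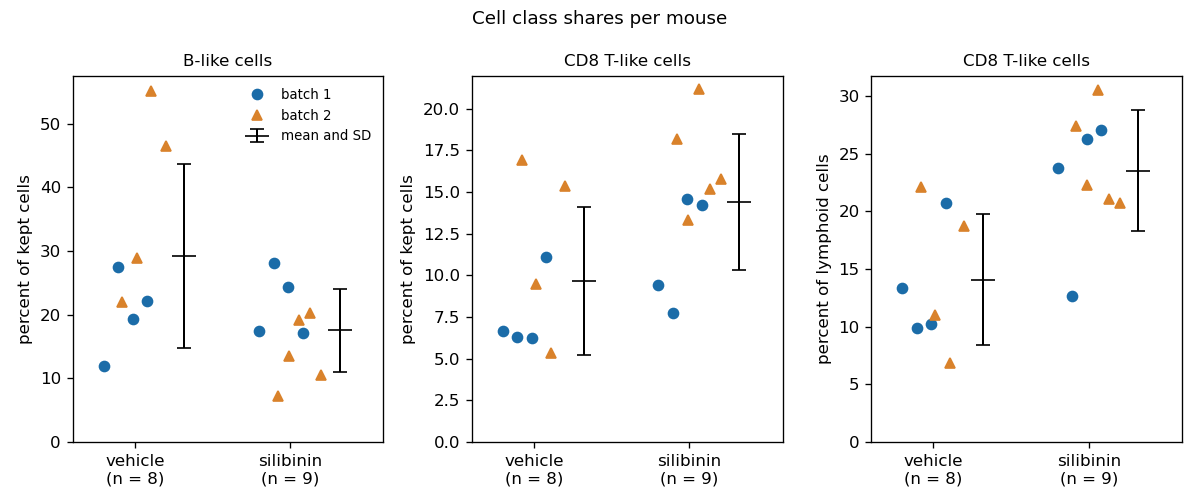
Percent of kept cells that were B-like (left) or CD8 T-like (middle), and percent of lymphoid cells that were CD8 T-like (right), one point per mouse, by group and technical batch, with group means and SD. CD8 T-like cells averaged 14.1% of lymphoid cells in vehicle mice and 23.5% in silibinin mice, and B-like cells in batch 2 averaged 38.2% of kept cells with vehicle and 14.2% with silibinin.

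Within technical batches, the B-like share differed by 1.57 percentage points in batch 1 (exact permutation p = 0.657) and by -24.0 points in batch 2 (exact permutation p = 0.0079, the smallest that batch allows). The CD8 T-like share of kept cells differed by 3.93 points in batch 1 (exact permutation p = 0.171) and 4.94 in batch 2 (exact permutation p = 0.143). As a share of lymphoid cells, CD8 T-like cells differed by 8.90 points in batch 1 (exact permutation p = 0.0857) and 9.76 in batch 2 (exact permutation p = 0.0317). When labels were permuted only within batch, the lymphoid share kept an adjusted exact p of 0.021. Permuted within run, the lymphoid share had an adjusted exact p of 0.109 (unadjusted 0.0219), so the call did not hold there.

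The other classes did not pass either. CD4 T-like cells averaged 12.9% ± 6.30 (SD, n = 8) of kept cells with vehicle and 12.1% ± 5.05 (SD, n = 9) with silibinin. NK-like cells averaged 9.38% and 10.1%, undivided T-like cells 7.76% and 7.21%, monocyte or macrophage-like cells 7.90% and 7.63%, neutrophil-like cells 6.65% and 8.03%, and dendritic-like cells 3.11% and 5.38%. Their adjusted exact permutation p-values lay between 0.517 and 0.946. edgeR applied to cell numbers called no class either, with adjusted p = 0.183 for B-like, CD8 T-like and dendritic-like cells.

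In reads summed over all kept cells, the 4 genes with the smallest p-values were genes of B cells, each lower in silibinin mice. Fcer2a was at a mean log2 CPM of 9.35 ± 1.18 (SD, n = 8) with vehicle and 7.90 ± 0.71 (SD, n = 9) with silibinin, a fitted log2 fold change of -1.77 ± 0.46 (SE). Ighd had a log2 fold change of -1.22 ± 0.33, Pax5, the transcription factor that holds B cell identity, -1.56 ± 0.44, and Cd79b, a signalling chain of the B cell receptor, -1.32 ± 0.41. No silibinin mouse lay above the vehicle median for any of these 4 genes. Further down stood Pou2af1 (-0.92 ± 0.36), a B cell coactivator, Blnk (-0.87 ± 0.35), an adaptor of B cell receptor signalling, Ccr7 (-0.93 ± 0.31), the lymph node homing receptor, and Myc (-0.60 ± 0.23), the growth regulator. None of 362 genes passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (smallest adjusted p = 0.284), with 17 genes at an unadjusted p under 0.05, 4 higher and 13 lower. DESeq2's Wald test called 3 genes, Fcer2a, Ighd and Pax5, each at an adjusted p of 0.0427. In batch 1 the log2 fold changes of Fcer2a, Ighd and Pax5 were -0.32, -0.12 and -0.74, and in batch 2 they were -2.39, -2.06 and -2.40, while Pou2af1 and Blnk were at 0.13 and 0.23 in batch 1 and -1.49 and -1.43 in batch 2. edgeR's test of the difference between batches called 0 of 362 genes, with 18 at an unadjusted p under 0.05 (adjusted p = 0.675, 0.426 and 0.81 for Fcer2a, Ighd and Pax5), and no other tool was run on it.

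**Figure D2:**
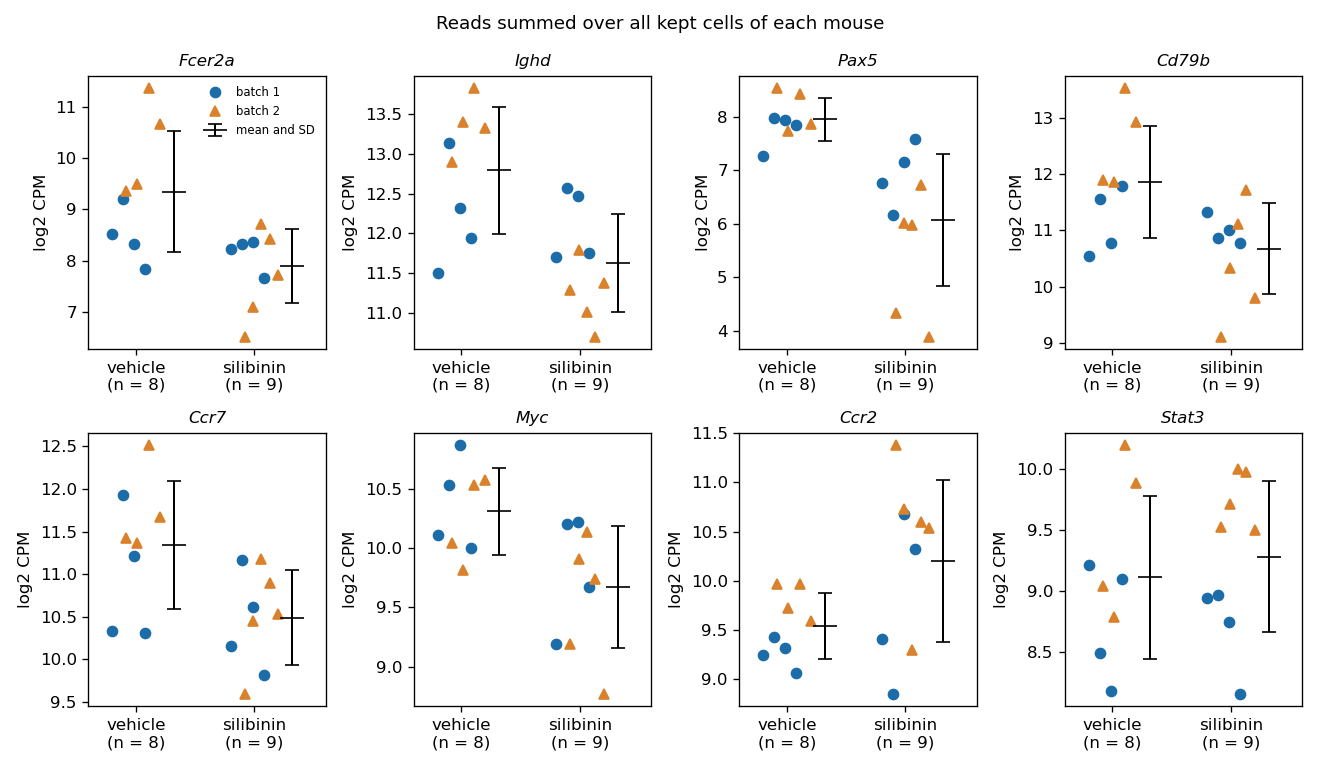
Log2 CPM of 8 genes in reads summed over all kept cells, one point per mouse, by group and technical batch, with group means and SD. Fcer2a averaged 9.35 with vehicle and 7.90 with silibinin, while Stat3 averaged 9.11 and 9.28.

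Among genes higher with silibinin, Ccr2, the chemokine receptor of inflammatory monocytes and of some T cells, had a log2 fold change of 0.82 ± 0.30 (adjusted p = 0.637 by edgeR, n = 8 and 9), with 0.78 in batch 1 and 0.83 in batch 2. Tmem97, the sigma-2 receptor, stood at 0.90 ± 0.38, Lgals3, the lectin galectin-3, at 0.69 ± 0.38, Gimap7, a lymphocyte GTPase, at 0.51 ± 0.29, and Zbtb16, a transcription factor of innate-like lymphocytes, at 1.26 ± 0.66. The antibody-secreting cell genes Jchain (9.09 ± 2.84) and Igha (8.53 ± 2.94) had high fitted values. So did Igkc (1.54 ± 0.82), a B cell transcript with reads in 95.3% of B-like cells. Igkc took 41.6% of the reads of silibinin 9, a mouse of batch 2 with 38 cells, and 17.9% in silibinin 3 of batch 1. Without silibinin 9 Igha stood at 0.63, Igkc at 0.21 and Zbtb16 at 0.19, and Jchain was too low to be tested, whereas in batch 1 alone Jchain was at 5.69, Igha at 1.51 and Igkc above its value in all mice.

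Genes tied to the drug's target and to T cell function did not pass in all cells, and several had wide errors. Stat3 had a log2 fold change of 0.14 ± 0.31 (95% interval -0.53 to 0.80), Cd8a 0.01 ± 0.28, Ifng 0.21 ± 0.24, Tnf 0.27 ± 0.44, Prf1 0.12 ± 1.25 and Gzmb 0.47 ± 0.43. The checkpoint genes Pdcd1, Lag3, Havcr2, Tigit, Ctla4 and Cd274 were at 0.15 ± 0.68, 0.04 ± 0.75, -0.25 ± 0.84, 0.29 ± 0.31, -0.02 ± 0.27 and 0.47 ± 0.44. Foxp3, the regulatory T cell factor, was at -0.24 ± 0.89, Mki67, a proliferation marker, at 0.13 ± 0.47, and the tetraspanin Cd63 at 0.55 ± 0.50. All had an edgeR adjusted p of 0.991. Without silibinin 9 the Cd274 value was -0.20.

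In CD8 T-like cells (8 vehicle and 8 silibinin mice), Gzma, Ikbkb and Egr1 had the smallest p-values among genes with higher values in silibinin mice, and Gzmk and Cd69 among those with lower values. Gzma, a granzyme, averaged a log2 CPM of 6.81 ± 3.66 (SD, n = 8) with vehicle and 10.96 ± 2.52 (SD, n = 8) with silibinin, a log2 fold change of 4.27 ± 1.59. Only 13.9% of CD8 T-like cells had Gzma reads, against 81.8% of NK-like cells, so that value rests on a minority of the class. Ikbkb, a kinase that activates NF-kappaB, was at 0.82 ± 0.32 and above the vehicle median in all 8 silibinin mice, and Egr1, an immediate early transcription factor, at 1.31 ± 0.52. In batch 1 and batch 2 the log2 fold changes were 4.86 and 2.22 for Gzma, 0.82 and 0.88 for Ikbkb, and 1.82 and 1.03 for Egr1. Lower values were found for Gzmk (-0.75 ± 0.37), the granzyme of memory-like CD8 T cells, Cd69 (-0.53 ± 0.27), an early activation and residency receptor, Fth1 (-0.42 ± 0.22), ferritin heavy chain, and Xcl1 (-0.84 ± 0.51), a chemokine for dendritic cells. None of 212 genes passed edgeR's test (all adjusted p = 0.997), with 3 at an unadjusted p under 0.05, and DESeq2 called 0.

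Other CD8 T-like values were Gzmb at 1.46 ± 0.79, Lgals1, galectin-1, at 0.77 ± 0.42, Cd160, an inhibitory receptor, at 0.91 ± 0.51, Gimap7 at 0.65 ± 0.37 and Zap70, the T cell receptor kinase, at 0.43 ± 0.26. Tnfsf8, Fosb, Trbc1 and Irf7 were at -2.42 ± 1.44, -0.66 ± 0.41, -0.52 ± 0.35 and -0.57 ± 0.40. Stat3 was at 0.35 ± 0.54 (its 95% interval, from -0.80, included a 2-fold rise), Cd8a at -0.12 ± 0.25, Ifng at 0.04 ± 0.34, Tnf at -0.92 (95% interval -3.49 to 1.65), Pdcd1 at -0.19 ± 1.09, Lag3 at 0.66 ± 1.27, Havcr2 at 2.44 ± 1.59, Tigit at 0.17 ± 0.54, Ctla4 at 0.42 ± 0.31, Cd274 at -0.29 ± 0.59 and Mki67 at -0.62 (95% interval -3.84 to 2.59).

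The inhibitory receptor and exhaustion list was the one list past camera's preset test in CD8 T-like cells. Of its 9 tested members 8 had positive log2 fold changes, with a median of 0.42, led by Cd160, Havcr2 and Ctla4 (adjusted p = 0.0188 by camera), while 0 members passed edgeR's gene test, adjusted over all genes or adjusted over the list alone. The list did not pass with an estimated correlation (adjusted p = 0.31 with an estimated correlation), and over all alternatives the adjusted p ran from 0.00774 to 0.31. Within batch 1 the camera adjusted p was 0.274 and within batch 2 it was 0.272. At a Leiden resolution of 1.5, 126 silibinin and 115 vehicle cells of the class fell into a CD8 T-like cluster and 100 and 44 into a CD4 T-like cluster, so the gene and list values also hold the mix of the 2. Leaving out vehicle 1, vehicle 3, vehicle 5, silibinin 1, silibinin 6 or silibinin 8 ended the preset call, at adjusted p of 0.0506, 0.122, 0.111, 0.0516, 0.08 and 0.158.

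The other CD8 T-like lists, of 14 tested, did not pass. For cytotoxic effector genes 5 of 12 members were positive (median -0.13, mean 0.27, camera adjusted p = 0.874), and for the STAT3 pathway and targets 4 of 9 were positive (median -0.20, camera adjusted p = 0.874), with Ccnd2, a cyclin, at -1.60 ± 1.13 and Myc at -0.74 ± 0.65. Naive and memory T cell genes were positive in 5 of 7 and regulatory T cell genes in 5 of 7. Immediate early genes were negative in 5 of 7, tissue residency genes in 5 of 8 and interferon response genes in 3 of 4. T cell activation and costimulation was positive in 5 of 10, chemokines in 3 of 5, chemokine receptors in 1 of 7, proliferation in 4 of 8, immunosuppressive myeloid genes in 2 of 5 and apoptosis genes in 4 of 8. For the chemokine receptors the median (-0.23) and mean (-0.38) were negative while camera's direction was up, and for proliferation the median was 0.02 and the mean -0.04.

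In all cells none of 17 lists passed camera. The MHC class II and antigen presentation list came closest, with all 7 members negative (median -0.46, adjusted p = 0.0538 by camera, 0.869 with an estimated correlation), beside a median of -0.90 for 20 B cell markers in all cells, and within B-like cells its median was -0.10 (adjusted p = 0.183 by camera). It was followed by proliferation, with all 8 positive (median 0.34, adjusted p = 0.091 by camera), and the interferon response, with all 5 positive (median 0.32, adjusted p = 0.134 by camera). The STAT3 pathway and targets were split, with 8 of 15 positive (median 0.02, mean -0.02, adjusted p = 0.958 by camera), and within it Myc was at -0.60, Rorc, the interleukin-17 lineage factor, at -0.91 ± 0.84 and Vegfa, a vessel growth factor, at -0.34 ± 0.43. Cytotoxic effector genes were positive in 9 of 13, with Klrg1 at -0.89 ± 0.69 and Gzmk at -0.41 ± 0.48, and inhibitory receptors in 5 of 10. T cell activation and costimulation was positive in 5 of 12, lymphocyte cytokines in 6 of 9, naive and memory T cell in 3 of 8, tissue residency in 3 of 8, regulatory T cell in 5 of 11, chemokines in 6 of 11 and chemokine receptors in 6 of 12. Mean and median had opposite signs for lymphocyte cytokines (-0.11 and 0.10), chemokine receptors (-0.05 and 0.03) and chemokines and inhibitory receptors, whose medians were 0.00. Inflammatory myeloid genes were positive in 5 of 11, immunosuppressive myeloid genes in 7 of 11, immediate early genes in 2 of 7 and apoptosis genes in 5 of 8. By fry no list in any fitted set passed.

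In B-like cells (8 vehicle and 8 silibinin mice) Fcer2a had a log2 fold change of -0.68 ± 0.26, with -0.34 in batch 1 and -0.95 in batch 2, and Lyz2, a lysozyme gene of myeloid cells, was at -3.96 ± 1.64. Lyz2 had reads in 4.58% of B-like cells, at a median of 4 where there were any, against 1369 in neutrophil-like cells. Tfrc, the transferrin receptor, was at 0.75 ± 0.34 and Pcna, a replication clamp, at 0.88 ± 0.45. edgeR called 0 of 182 genes (3 at an unadjusted p under 0.05) and DESeq2 called 0. The proliferation list passed camera's preset test, with 5 of 6 members positive and a median of 1.02, including Top2a (3.13 ± 1.59) and Mcm2 (1.15 ± 0.71), at an adjusted p of 0.0247. It did not pass with an estimated correlation (adjusted p = 0.669 with an estimated correlation) or with batch as a term (adjusted p = 0.0609), and over all alternatives the adjusted p ran from 0.00105 to 0.89. In batch 1 and batch 2 the log2 fold changes were -0.05 and 1.33 for Pcna, -0.56 and 3.47 for Top2a, and -0.50 and 1.56 for Mcm2, with a camera adjusted p of 0.89 and 0.00811. Leaving out vehicle 3, vehicle 5, vehicle 7, vehicle 8, silibinin 3, silibinin 7 or silibinin 8 ended it, at adjusted p of 0.215, 0.0926, 0.0734, 0.1, 0.0521, 0.522 and 0.565.

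In neutrophil-like cells (4 vehicle and 4 silibinin mice, 3 and 3 of them in batch 1) 5 lists passed camera's preset test and 0 of them did with an estimated correlation. All 8 tested chemokines had negative log2 fold changes (median -2.11, adjusted p = 0.00305 by camera, adjusted p = 0.244 with an estimated correlation), among them Ccl4 (-1.80 ± 0.67), Ccl3 (-1.62 ± 0.68) and Ccl5 (-5.14 ± 1.95), which attract monocytes and T cells. Gzma, a lymphocyte granzyme, moved in the direction of Ccl5 there, from a mean of 654 CPM with vehicle to 2.17 with silibinin (-8.14 ± 2.38), against 492 and 13.8 for Ccl5. Few neutrophil-like cells held such reads: 6.04% had Gzma and 8.05% had Ccl5, at medians of 4 and 8 reads where there were any. In NK-like cells those medians were 1892 and 2833. Both values therefore rest on few cells, and whether these reads came from lymphocytes was not tested. All 8 proliferation genes were positive (median 1.74, adjusted p = 1.02e-05 by camera, adjusted p = 0.244 with an estimated correlation), with Top2a at 3.84 ± 1.88, Ube2c at 2.73 ± 2.08 and Mcm2 at 1.83 ± 1.49. Inflammatory myeloid genes were negative in 8 of 9 (median -1.31, adjusted p = 0.0114 by camera, Nlrp3 at -1.31 ± 0.60), immediate early genes in 6 of 6 (median -0.66, adjusted p = 0.0416, Junb at -1.30 ± 0.68) and inhibitory receptors in 4 of 4 (median -1.50, adjusted p = 0.0416, Havcr2 at -3.57 ± 2.75). With an estimated correlation none of the 5 lists passed (adjusted p = 0.244 with an estimated correlation for the first 4 and 0.292 for the last). In batch 1 alone the proliferation list kept an adjusted p of 3.1e-05, while the chemokine list stood at 0.0815 and the inflammatory myeloid and immediate early lists at 0.167, all by camera. Batch 2 held 1 mouse per group and gave no value.

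Single genes in neutrophil-like cells did not pass. S100a8 was at 0.93 ± 0.38, and Psen1, a protease subunit, at 0.97 ± 0.47. As a measure of background, S100a8 reads were found in 32.6% of B-like cells, at a median of 7 reads where there were any, and took 0.0022% to 0.377% of a mouse's B-like reads. edgeR called 0 of 187 genes (6 at an unadjusted p under 0.05), while DESeq2 called 1, Gzma, which had reads in 6.04% of neutrophil-like cells. Leaving out vehicle 1 put the chemokine list at an adjusted p of 0.0775 and the inflammatory list at 0.131, and leaving out silibinin 6 put them at 0.123 and 0.251, whereas the proliferation list reached at most 0.000593 in all 8 fits by camera. The immediate early list was lost without vehicle 1, vehicle 2, vehicle 8, silibinin 1 or silibinin 6 (adjusted p = 0.131, 0.0846, 0.126, 0.17 and 0.251), and the inhibitory receptor list without vehicle 1, vehicle 2, vehicle 6, silibinin 1, silibinin 3, silibinin 4 or silibinin 6 (adjusted p = 0.131, 0.0846, 0.155, 0.073, 0.176, 0.0637 and 0.0735).

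In the other T and NK classes no gene passed either. CD4 T-like cells (8 and 7 mice) had Lgals3 at 1.53 ± 0.80, Itk, a T cell receptor kinase, at 0.42 ± 0.24, Alas2, a haem synthesis enzyme of red cells, at -3.74 ± 2.05 and Igkc, a B cell transcript, at -4.05 ± 1.54, with 0 of 211 genes called by edgeR, 1 at an unadjusted p under 0.05 and 0 by DESeq2. Igkc had reads in 11.8% of CD4 T-like cells, at a median of 5 where there were any, against 3442 in B-like cells. Undivided T-like cells (5 and 5 mice) had Trbc1, a T cell receptor chain, at -1.73 ± 0.49, Ccr7 at -1.05 ± 0.35, Pik3ip1, an inhibitor of PI3 kinase, at 0.88 ± 0.38 and Selplg, the selectin ligand PSGL-1, at 0.60 ± 0.33, with 0 of 154 genes called by edgeR, 5 at an unadjusted p under 0.05 and 0 by DESeq2. Within the chemokine receptor list Ccr7 reached 0.0423 adjusted over the list alone. NK-like cells (7 and 6 mice) had Dusp2, a phosphatase, at 0.59 ± 0.21, Irf7, an interferon regulator, at 1.37 ± 0.53, Cxcr6, a tissue residency chemokine receptor, at -1.59 ± 0.68 and Ighm at -0.91 ± 0.45, with 0 of 203 genes called by edgeR, 5 at an unadjusted p under 0.05 and 0 by DESeq2.

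Monocyte or macrophage-like cells (5 and 5 mice) had Spp1, the secreted protein osteopontin, at a log2 fold change of 5.62 ± 2.19, with reads in 2 of 5 vehicle and 5 of 5 silibinin mice, and Mcm2, a replication helicase subunit, at 2.48 ± 0.74. Tmem173, the DNA sensor adaptor STING, was at -0.82 ± 0.30 and Selplg at -0.82 ± 0.32. edgeR called 0 of 201 genes (4 at an unadjusted p under 0.05) and DESeq2 called 0, and Mcm2 alone passed within the proliferation list adjusted over the list alone (0.0493 by edgeR). Chemokine genes were positive in 8 of 9 members (median 0.70, adjusted p = 0.143 by camera), and the STAT3 pathway and targets negative in 8 of 8 (median -0.17, adjusted p = 0.196 by camera). Dendritic-like cells reached 10 cells in 2 vehicle and 4 silibinin mice and were not fitted.

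Technical batches differed in more genes than treatments did. In all cells 68 of 362 genes differed between batches by edgeR. They were led by Cd2, an adhesion receptor of T and NK cells (log2 fold change 1.55, batch 2 over batch 1), Bin2 (1.06), Egr1 (-2.25), Cxcr6 (1.82) and Cd14 (-2.47), a monocyte receptor. The batches also differed in cell makeup. Monocyte or macrophage-like cells averaged 12.9% (vehicle) and 14.8% (silibinin) of kept cells in batch 1, and 2.88% and 1.86% in batch 2. How many of the 68 genes followed from makeup was not tested. With batch as a term in the treatment comparison the count of genes past the threshold was still 0 by edgeR.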

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

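The test of the left-out barcodes was chosen only after the data were seen. A total of 19 values stood far from the rest of their group among 160 groups of values tested. For normally distributed values chance flags about 1 in 20 groups. Several flagged values were of genes without reads, which the prior count places far below the rest. That rate does not apply to such values, so no excess over chance can be read from the count.

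Silibinin 9, the mouse with 38 cells, accounts for several of the flagged values. Undivided T-like cells made up 26.3% of its cells against at most 9.15% in the other silibinin mice, and Igkc took 41.6% of its reads against at most 17.9%. In its summed reads Cd274 stood at 11.48 log2 CPM, above 9.34 in the next mouse, while Lag3 and Klrg1 had no reads, which the prior count places at -1.66. Silibinin 1 had the highest monocyte or macrophage-like share of its group, 26.8%, and the most reads per kept cell, with a median of 37111 against at most 22506 in the other silibinin mice. In vehicle 8, S100a8 took 46.0% of all reads against at most 27.2% in the other vehicle mice, and Gimap7 was at 8.09 log2 CPM, the lowest of its group.

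Other values far from their group in all cells were Ifng at 11.36 log2 CPM in vehicle 3, Gzmk at 10.09 in vehicle 7, and Havcr2 in vehicle 4, Foxp3 in silibinin 8 and Rorc in silibinin 3, each without reads and placed at -1.66. In CD8 T-like cells Tigit was at 6.58 in vehicle 5 and Gimap7 at 9.55 in silibinin 2. Ccnd2 in vehicle 8 and in silibinin 3 and Pdcd1 in silibinin 2 had no reads there, which the prior count places at 1.82.

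The 2001 barcodes with reads of fewer than 10 panel genes entered only the alternative without a filter on genes per cell. Among them 99.0% had reads of Alas2, 84.8% of Slc25a37, the mitochondrial iron carrier, and 90.5% of Fth1. Of these barcodes 1996 came from the 8 mice of batch 1.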

How the results depend on the processing

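Batch and run fits, each batch alone, cells thinned to 5000 reads, the Scrublet alternative, the fit without neutrophil-like cells and the list fits without single mice were chosen after seeing the data. The number of classes past the threshold, 0, held in all runs except percent of lymphoid cells, which gave 1 (CD8 T-like). Genes past the threshold stayed at 0 in every set except for 3 in all cells by DESeq2 and 1 in batch 2 alone, and in neutrophil-like cells 1 by DESeq2 and 10 with run as a block, a fit that leaves 1 residual degree of freedom. The cause of those differences was not tested. Without single mice all class and gene counts stayed at 0, and the CD8 T-like share of lymphoid cells kept an adjusted exact p of 0.0039 to 0.0424.

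Lists past camera's preset test, 7 over all sets, numbered 0 with an estimated correlation and 2 with run as a block. In all cells the count went from 0 to 2 in batch 1 alone, 2 in batch 2 alone, 1 with DESeq2 size factors and 2 without neutrophil-like cells. Without single mice it ranged from 0 to 3, with 3 without silibinin 5, 2 without silibinin 2 and 1 without vehicle 2, vehicle 3, vehicle 4, vehicle 8 or silibinin 3. In CD8 T-like cells it went from 1 to 0 with an estimated correlation, in batch 1 alone and in batch 2 alone, and ranged from 0 to 1, with 0 without vehicle 1, 3 or 5 or silibinin 1, 6 or 8. In B-like cells it went from 1 to 0 with an estimated correlation, the batch term, run as a block and batch 1 alone, to 2 in batch 2 alone, and ranged from 0 to 2, with 2 without silibinin 1 or 2 and 0 without vehicle 3, 5, 7 or 8 or silibinin 3, 7 or 8. In neutrophil-like cells it went from 5 to 0 with an estimated correlation, to 1 in batch 1 alone and to 1 with run as a block, and ranged from 1 to 5, with 1 without vehicle 1 or silibinin 6 and 3 without vehicle 2 or silibinin 1. It ranged from 0 to 1 in CD4 T-like cells (1 without vehicle 7 or silibinin 4), undivided T-like cells (1 without vehicle 4 or 5) and monocyte or macrophage-like cells (1 without vehicle 1 or silibinin 4). The cause was not tested.

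With the replicate number as a block, 0 classes and 0 genes passed in every set, and 6 lists did, with 1 in CD4 T-like cells in place of 0, 0 in B-like cells in place of 1 and 4 in neutrophil-like cells in place of 5. Mice of the same number correlated between -0.43 and 0.31, over 0.1 in 5 of 8 pairs, and 1 of 8 vehicle mice correlated best with its own number, so the numbers were not taken to pair the mice. Vehicle and silibinin mice of one run had a median correlation of 0.22, against -0.07 for those of other runs. For another run of the same batch the median was 0.14. None of the 7 called lists changed its camera direction, although Pcna, Top2a and Mcm2 of the B-like proliferation list were negative in batch 1 alone. Values short of the threshold did change sign, among them Igha in all cells (-2.51 with run as a term), Junb in neutrophil-like cells (0.24 with run as a term) and the B-like share (1.57 points in batch 1 alone). Fits with at least 20 cells per mouse could not be made for undivided T-like cells, and Scrublet's planned call was not run. Of simulated 2-fold differences 8% were called in CD8 T-like cells and 18% in all cells, and what part of this depth sets was not tested.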

Other observations

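All tests of explanations below, the cluster comparisons and the permutations within batch were chosen only after the results were seen. A cluster of 318 cells without a class name, with 5 NK markers among its 10 leading genes and Cd3d reads in 89.3% of cells, was led by Trdc, the delta chain of the T cell receptor, Cd160, Klrc1, an inhibitory NK receptor, and Xcl1. It made up 6.63% ± 3.58 (SD, n = 8) of kept cells with vehicle and 11.4% ± 4.28 (SD, n = 9) with silibinin, higher than the vehicle median in 8 of 9 mice, with an exact permutation p of 0.0279 (adjusted 0.222 over 17 clusters). Permuted within batch its exact p was 0.001 (adjusted 0.0173), with differences of 3.30 points in batch 1 and 5.43 in batch 2, but at a Leiden resolution of 1.5 the cluster led by Trdc and Klrc1 (345 cells) had an adjusted exact p of 0.188 within batch. edgeR, the one tool run on it, called 0 of its 199 tested genes, with 2 at an unadjusted p under 0.05.

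A cluster of 50 cells led by Il1rl1, the interleukin-33 receptor, Ccr8, Arg1 and Kit averaged 0.797% with vehicle and 2.05% with silibinin (exact permutation p = 0.0364, adjusted 0.222). The third unnamed cluster, 146 cells with few reads led by F5 and Thbd, averaged 5.25% and 3.09% (exact permutation p = 0.328). At that resolution 126 silibinin and 115 vehicle cells of the CD8 T-like class fell into a CD8 T-like cluster, and 100 and 44 into a CD4 T-like cluster. That CD4 T-like cluster, of 162 cells in all, averaged 2.72% ± 2.12 (SD, n = 8) of kept cells with vehicle and 5.94% ± 3.49 (SD, n = 9) with silibinin (exact permutation p = 0.0399, adjusted 0.328).

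The higher CD8 T-like share of lymphoid cells was weighed against technical explanations. A difference in reads per cell stays open. After thinning to 5000 reads per cell the CD8 T-like share differed by 9.13 points (adjusted exact permutation p = 0.0196). The CD8 class then also held the cluster of naive T cell genes, and averaged 25.3% of lymphoid cells with vehicle and 34.4% with silibinin. Thinning therefore did not test the class as first drawn. Fewer B-like cells in the denominator stays open, since among T and NK classes alone the difference was 9.38 points with an exact permutation p of 0.0666. Cells of the class with Cd4 reads also stay open, since neither part passed after adjustment. Cells with Cd8 reads and none of Cd4 differed by 5.04 points of lymphoid cells (exact permutation p = 0.0551, adjusted 0.22). Those with Cd4 reads and none of Cd8 differed by 3.04 points (exact permutation p = 0.0097, adjusted 0.0777). A larger fraction of CD8 T cells with silibinin may be part of the pattern, as a hypothesis these data leave open.

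The lower B cell genes in summed reads go with fewer B-like cells for the markers as a set. The median log2 fold change of 20 B cell markers was -0.90 in all cells and 0.0146 within B-like cells, with 19 and 9 of them negative. The leading genes stayed negative within B-like cells, though less so: Fcer2a was at -0.68, Pax5 at -0.60, Cd79b at -0.26 and Ighd at -0.19. Clusters were named by B cell markers and reads were normalised within the class, which limits what that median can show. Whether cell number alone accounts for the leading genes was not tested. A difference carried by batch 2 alone stays open: the B-like share difference differed between batches by -25.6 points (exact p = 0.0145, adjusted 0.116 over 8 classes), and edgeR's test between batches called 0 of 362 genes (18 at an unadjusted p under 0.05). Whether the sort or the bead depletion explains this was not tested, because the labels do not give the route per mouse. A fall of B cells with silibinin stays open beside these, as an untested hypothesis.

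The neutrophil-like lists were weighed against the mix of 2 clusters within the class. The cluster led by Chil3, a secreted lectin of maturing neutrophils, took 36.3% ± 40.3 (SD, n = 4) of the class's reads with vehicle and 60.6% ± 17.8 (SD, n = 4) with silibinin. The difference was 24.3 points (exact permutation p = 0.314), so a shift in the mix stays open. Per mouse the cluster took 3.10%, 6.01%, 47.9% and 88.4% in vehicle 1, 2, 8 and 6, and 45.1% to 85.4% in silibinin mice. More reads of that cluster would go with the directions of the proliferation, chemokine and inflammatory lists. Mki67 had reads in 24.7% of its cells and in 0% of the other cluster's cells. Il1b and Cxcl2, of the inflammatory and chemokine lists, were among the genes that led the other cluster. Fits within single clusters, with at least 5 cells per mouse, were too small to decide on the mix. In the Chil3-led cluster (3 and 4 mice) the camera adjusted p was 0.206 for the proliferation and chemokine lists (0.00234 for chemokines as the mean over cells). In the other cluster (3 and 5 mice) it was 0.0497 for the chemokine list. Of the 35 splits of these 8 mice, 1 gave as many lists, the real one with 5, and the highest other gave 4, but of the 20 splits that keep the batches balanced 1 did (highest other 4), too few splits for a share under 0.05. An effect of silibinin on neutrophils stays open, untested.

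Random splits could account for the other list counts. In CD8 T-like cells 36 of 100 splits gave at least the real 1 list (highest other 4), and 26 of 100 did when the batches were kept balanced (highest other 4). In B-like cells 26 of 100 splits did (highest other 2), and 26 of 100 with balanced batches (highest other 3). Where the real split called 0, every split is as large by definition, so the 100 of 100 splits for genes (35 of 35 in neutrophil-like cells) and for lists say nothing of chance. The highest other gene counts were 13 in all cells, 1 in CD8 T-like, 2 in CD4 T-like, 1 in undivided T-like, 1 in NK-like, 2 in B-like, 1 in monocyte or macrophage-like and 0 in neutrophil-like cells, and the highest other list counts 4 in all cells and 3, 3, 2 and 3 in CD4 T-like, undivided T-like, NK-like and monocyte or macrophage-like cells. The split with 13 genes nearly followed the technical batches, a structure other than treatment, with 7 of 9 mice of batch 2 on one side and 7 of 8 of batch 1 on the other.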
